A study of Mus musculus with 6 samples.

How the data were processed

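RNA was measured by sequencing in CD4+ SMARTA T cells, which carry a transgenic T cell receptor for an epitope of lymphocytic choriomeningitis virus (LCMV), and which lacked Bcl6, the transcriptional repressor that directs follicular helper T cell (Tfh) differentiation. The cells came from C57BL/6 mice on day 7 of LCMV infection. The 6 libraries form 3 groups of 2: spleen, the intraepithelial lymphocyte fraction of the small intestine (IEL) and its lamina propria lymphocyte fraction (LPL). Groups and replicate numbers were taken from the sample titles. No wild-type group is among the 6 libraries, so no effect of Bcl6 loss was tested. Per the labels, total RNA was extracted in TRIzol and libraries were made with a PrepX RNA-seq kit. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be in part technical.

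The deposited table held TPM (reads per gene divided by gene length and scaled to a fixed total per library by the authors). This was read from the values: the 6 columns summed to between 987011 and 997190, and the smallest values depended on gene length. Per the submitters' processing notes, Bowtie2, STAR, featureCounts and DESeq2 were used with the mouse build mm10. Their roles and versions are not given in the sources used here, and neither is the filter that left 11560 rows. Of these rows, 14 carried a date in place of a gene symbol and 641 were small RNA genes. No mitochondrially encoded gene was listed (0 rows). Symbols were matched to GENCODE M21, which covers the same build, for 11150 rows (96.5%), and coordinates are 1-based from that annotation. Near-identical paralogs, overlapping genes and antisense genes may share reads, because the counting and strand settings are not given.

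TPM keep no total depth. In 895 single-exon genes, TPM multiplied by annotated length came in steps, and between 61.6% and 79.3% of values below the fifth step lay within 2% of a whole multiple. For a transcript of 2000 bp, 1 read was worth 0.1 and 0.15 TPM in spleen replicates 1 and 2, 0.36 and 0.29 in IEL, and 0.09 and 0.28 in LPL. IEL replicate 1 was the shallowest library by this measure, and LPL replicate 1 was 4.08 times deeper. Values near these steps rest on single reads. Counting intervals were not derived from these steps.

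The planned test was a count model. Because the table held TPM, the fallback fixed with it was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(TPM + 1), with all 6 libraries in 1 model of group means and no block. Fold changes are on that scale, which understates changes of low genes. The 95 rows at 0 in every library were removed and 11465 genes were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 comparisons were IEL against spleen, LPL against spleen and IEL against LPL. For single values, an exact permutation of 2 against 2 libraries cannot go below p = 0.333. Of 28 gene lists, 26 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction. The erythroid marker list had 1 tested member and was not tested as a list.

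The test was tried on simulated data for IEL against spleen, drawn for the 11465 genes from the fitted means and spreads, with 200 changed genes in each of 10 runs. It called 33% of genes changed by 1 on the log2 scale, 91% of those changed by 2 and 97.7% of those changed by 3, and 7.6% of its calls were false. With spleen replicate 1 left out, it called 9.1%, 73.3% and 89.1%. A residency list shifted by 1 was called in 10 of 10 runs, in which 8 calls also fell on other lists. Some of those lists share shifted members with the residency list, so whether these 8 calls were false cannot be told. The simulated genes were independent, so these runs do not test the effect of inter-gene correlation.

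Before the data were examined, the gene lists, the tests, most alternatives and the rule for named genes were fixed. The rule took Bcl6; the 10 largest called changes in each direction with a group mean of at least 10 TPM and no overlap between groups, leaving out predicted genes, receptor segments and markers of other cells; up to 4 members of each list by smallest adjusted p; and 12 markers whatever their result. The 10 TPM minimum stood as CPM in the rule. Not all genes the rule allows are named, and some are not reported here. Alternatives were other scalings, pseudocounts, filters, models and the omission of each library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.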

Results

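Gene expression was compared among Bcl6-deficient SMARTA CD4+ T cells recovered on day 7 of LCMV infection from the spleen, the small intestinal epithelium (IEL) and the small intestinal lamina propria (LPL), with 2 libraries per group. Values are TPM, given as mean ± SD with n = 2. Between 9920 and 10841 genes reached 1 TPM in a library. Pearson correlations across genes of log2(TPM + 1) were 0.944 between the spleen libraries, 0.955 between the LPL libraries and 0.882 between the IEL libraries. IEL replicate 1 correlated more closely with LPL replicates 1 (0.9) and 2 (0.885) than with its own replicate. IEL replicate 2 correlated more closely with the spleen libraries (0.913 and 0.918) and the LPL libraries (0.931 and 0.936) than with IEL replicate 1. The IEL libraries thus did not group together, and IEL means average unlike profiles. The targeted gene, Bcl6 (chromosome 16, 23965052 to 23988852, minus strand), was at 38.2 and 22.9 TPM in the spleen libraries, 31.8 and 18 in IEL and 47.4 and 29.4 in LPL. Which exons were deleted is not given in the labels, and a gene-level value cannot separate them, so these values do not check the deletion.

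The first comparison asked how T cells of the intestinal epithelium differed from those of the spleen. Several genes linked to tissue residency were higher in IEL. Rgs1, a regulator of G protein signalling (chromosome 1, 144242296 to 144249242), was at 2130 ± 148 TPM in IEL and 88.2 ± 7.48 in spleen, a log2 fold change of 4.58 (SE 0.17, adjusted p = 0.000156). Ccr9, the receptor for the gut chemokine Ccl25, rose by 5.02, Itgae, the alpha E integrin chain CD103, by 3.48, and Cd69, which restrains S1pr1 at the cell surface, by 3.73. S1pr1, the receptor for lymphoid egress (chromosome 3, 115710433 to 115715072), fell by 1.62 (SE 0.25, adjusted p = 0.0189), from 404 ± 14.2 to 135 ± 46.4 TPM.

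Of 33 tested residency genes, 18 were higher in IEL and 0 lower (27 and 0 adjusted over the list alone; camera adjusted p = 1.24e-30, adjusted p = 0.165 with an estimated correlation). Cish, a cytokine signalling inhibitor, rose by 2.67, and Rgs2 by 3.76. Of 28 immediate-early genes, 19 were higher and 0 lower (22 and 0 adjusted over the list alone; camera adjusted p = 1.26e-24, adjusted p = 0.252 with an estimated correlation), including Nr4a2 (log2 fold change 6.15, SE 0.41), Nr4a1 (4.80) and Nfkbiz (2.81). The residency list shares 5 members with the immediate-early list, and all 5 were higher. Of 15 genes of the TGF-beta response, 6 were higher (6 higher and 1 lower adjusted over the list alone), among them Tgif1 (4.12), Skil (3.35) and the inhibitory Smad7 (2.01). The camera adjusted p was 0.000129, and the adjusted p = 0.252 with an estimated correlation. Of 23 genes of cholesterol synthesis and uptake, 10 were higher (14 adjusted over the list alone), among them Insig1 (3.12) and the synthesis enzyme Cyp51 (2.32), with a camera adjusted p of 6.54e-12 and an adjusted p = 0.252 with an estimated correlation. Of 16 heat shock genes, 3 were higher (7 adjusted over the list alone): Hspa5, Dnaja1 and Dnajb4, by 1.19, 1.64 and 1.64. The camera adjusted p was 5.43e-08, and the adjusted p = 0.369 with an estimated correlation.

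Of 31 tested genes of circulation and egress, 7 were lower and 1 higher in IEL (19 and 1 adjusted over the list alone; camera adjusted p = 1.3e-10, adjusted p = 0.252 with an estimated correlation). Klf2, which drives S1pr1 transcription, fell by 2.13 (SE 0.43, adjusted p = 0.0499), and Arhgef18 fell by 1.66. The member that rose was Dusp5, a phosphatase of ERK, by 2.37. Of 40 proliferation genes, 4 were lower and 0 higher (17 and 0 adjusted over the list alone; camera adjusted p = 7.25e-12, adjusted p = 0.687 with an estimated correlation). Among genes that act in mitosis, Plk1 fell by 2.57, Cdc20 fell by 1.72 and Ube2c fell by 1.72. The Tfh list had a camera adjusted p of 0.0289 in the lower direction and an adjusted p = 0.687 with an estimated correlation, although 0 of its 27 tested members were lower over all genes and Icos, a costimulatory receptor, rose by 1.46. Adjusted over the list alone, 2 were higher and 2 lower. The list no longer passed without spleen replicate 1 (adjusted p = 0.28), IEL replicate 1 (0.11) or IEL replicate 2 (0.224). The spleen libraries differed in members of this list: Tcf7 was at 413.5 TPM in replicate 1 and 56.4 in replicate 2.

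Genes of the Th1 and cytotoxicity lists went both ways, which does not by itself give a direction of effector function. Fasl rose by 2.30 and Gzmk by 1.26, while Id2, a regulator of effector differentiation, fell by 1.23 and Klrc1, a receptor on the cytotoxicity list, fell by 1.31. For Gzmb the log2 fold change was 0.50 (SE 0.45), for Tbx21 it was -0.01 (SE 0.61), for Prdm1 1.12 (SE 0.27), for Ifng 1.08 (SE 0.23), and for Cxcr6 -0.14 (SE 0.16), none past the threshold. Gzmb was higher in replicate 2 and Tbx21 in replicate 1 in all 3 tissues, and without a block the SE includes such differences. Gzmb was at 2155 and 4369 TPM in spleen replicates 1 and 2 and at 3096 and 6116 in IEL. Compared within replicate numbers, Gzmb was thus higher in IEL both times, whereas Tbx21 went both ways. The Th1 list (3 higher and 1 lower of 25), the memory-associated list (2 and 2 of 20), the cytotoxicity list (3 and 2 of 21), the glycolysis list (0 of 22) and the oxidative phosphorylation list (0 of 46) did not pass camera. Small RNA genes that the rule for the largest changes also selected, such as Mir18, rested on few reads and are not described.

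Over all genes, limma called 235 genes higher and 97 lower in IEL, with 2001 genes at an unadjusted p under 0.05 where 573 would be expected by chance. Epithelial transcripts differed between the libraries of a group. The 38 tested enterocyte, Paneth and goblet markers had a median of 0 TPM in spleen replicate 1 and 15 in spleen replicate 2. Their medians were 5.45 and 7.73 in the IEL libraries, and 0 and 4.13 in the LPL libraries. For 338 olfactory, vomeronasal and taste receptor genes, the median was 7.54 TPM in IEL replicate 1 and 0 in IEL replicate 2. The 5.45 TPM of IEL replicate 1 therefore cannot be told apart from the level of such genes in that library. Neither epithelial list passed camera here (adjusted p of 0.18 and 0.182). Without spleen replicate 2, the enterocyte list (adjusted p = 1.31e-07) and the Paneth and goblet list (4.73e-06) were higher in IEL, and without spleen replicate 1 the enterocyte list was lower (0.026). The number of calls depended on the libraries in the model, including those outside the comparison. With only the IEL and spleen libraries in the fit, which leaves both group means unchanged, 22 genes were called higher and 1 lower. A fall in calls therefore does not by itself show that they rest on a given library. With each of the 6 libraries left out in turn, LPL libraries included, fewer genes were called than in the full fit, and in some fits none. Without IEL replicate 2, the calls were mostly other genes than those of the full fit. The residency, immediate-early, egress, cholesterol, heat shock, TGF-beta and proliferation lists kept their direction and passed camera at the preset correlation in all 6 of these fits, in some of which 0 of their members were called. With an estimated correlation, none of the 26 lists passed (0 lists, smallest adjusted p = 0.165). By fry, the residency (adjusted p = 0.00985), egress (0.026), TGF-beta (0.026), cholesterol (0.026) and immediate-early (0.0265) lists passed. The proliferation (0.28), heat shock (0.0537) and Tfh (0.498) lists, which passed camera, did not pass fry.

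**Figure D1:**
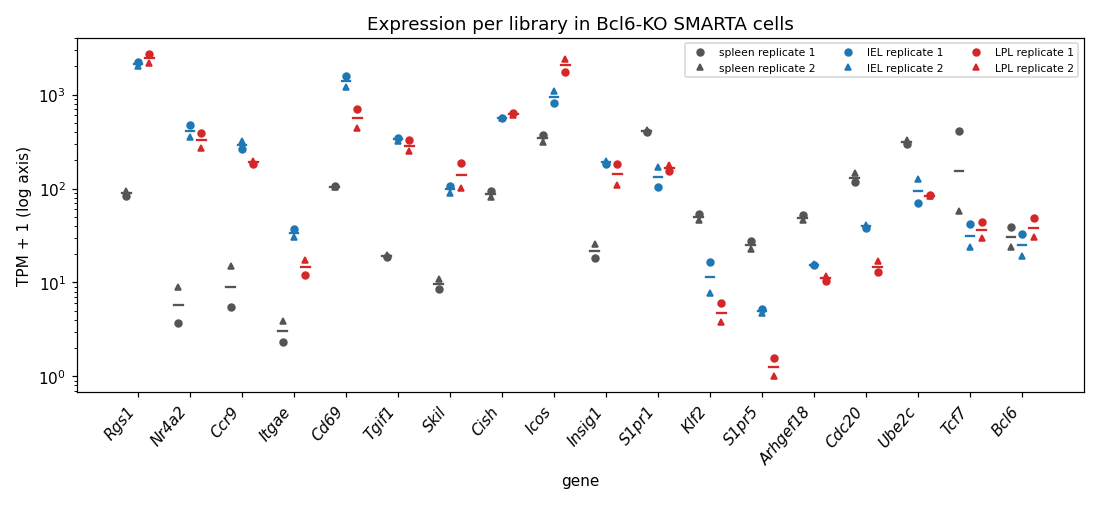
TPM + 1 on a log axis for 18 genes in each of the 6 libraries; colours mark the 3 groups, circles replicate 1, triangles replicate 2, and short lines the geometric mean of the 2 libraries. Rgs1 lay between 82.9 and 93.4 TPM in spleen and between 2025 and 2705 TPM in the intestinal libraries, while Tcf7 was at 413.5 TPM in spleen replicate 1 and 56.4 TPM in spleen replicate 2.

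The second comparison set LPL against spleen. Ramp3, which modifies calcitonin family receptors (chromosome 11, 6658521 to 6677475), had the largest rise among the genes the rule selected, from 2.91 ± 1.31 TPM in spleen to 520 ± 155 in LPL, a log2 fold change of 7.07 (SE 0.31, adjusted p = 0.000241). Dgat1, which makes triacylglycerol and retinyl esters (chromosome 15, 76502015 to 76511953), rose by 5.34 to 3240 ± 78.5 TPM. Calca, which encodes calcitonin and CGRP, rose by 4.63, and Irg1, the itaconate-producing enzyme, by 4.68. Which cells the Irg1 transcripts came from was not tested. Among 9 tested myeloid markers, 1 was higher in LPL (Xcr1, by 1.53) and 0 were lower. The myeloid list did not pass camera (adjusted p = 0.976). Rgs1 rose by 4.77, Ccr9 by 4.40, Cd69 by 2.41, Itgae by 2.26 and the chemokine receptor Cxcr6 by 0.88. S1pr5 fell by 4.33, Klf2 fell by 3.39 and S1pr1 fell by 1.29.

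Of 33 residency genes, 21 were higher in LPL and 0 lower (26 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.04e-26, adjusted p = 0.21 with an estimated correlation). Litaf rose by 3.20 and Cish by 2.82. Of 31 egress genes, 18 were lower and 1, Dusp5, was higher (25 and 1 adjusted over the list alone; camera adjusted p = 3.67e-11, adjusted p = 0.221 with an estimated correlation), and Rap1gap2 fell by 3.42 while Cmah fell by 3.70. Of 40 proliferation genes, 19 were lower and 0 higher (34 and 0 adjusted over the list alone; camera adjusted p = 9.63e-12, adjusted p = 0.562 with an estimated correlation). Cdc20 fell by 3.15 and the mitotic kinase Aurkb fell by 2.15. Outside the list, E2f2, a transcription factor of the cell cycle, fell by 3.86 and the mitotic kinase Pbk fell by 4.44.

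Immediate-early genes were higher for 16 of 28 and lower for 0 (camera adjusted p = 4.5e-14, adjusted p = 0.329 with an estimated correlation), and adjusted over the list alone 17 were higher and 1 lower. TGF-beta response genes were higher for 8 and lower for 1 of 15 (10 and 1 adjusted over the list alone; camera adjusted p = 3.75e-07, adjusted p = 0.221 with an estimated correlation), and Pmepa1, a feedback inhibitor, rose by 3.78. Cholesterol genes were higher for 9 of 23 (12 adjusted over the list alone; camera adjusted p = 2.72e-07, adjusted p = 0.329 with an estimated correlation) and heat shock genes higher for 6 and lower for 1 of 16 (8 and 1 adjusted over the list alone; camera adjusted p = 6.26e-07, adjusted p = 0.329 with an estimated correlation). On the regulatory T cell list, 5 were higher and 2 lower of 11 (6 and 3 adjusted over the list alone; camera adjusted p = 0.00309, adjusted p = 0.329 with an estimated correlation). The costimulatory receptors Tnfrsf4 and Tnfrsf18 on that list rose by 3.25 and 1.34, and Ctla4 by 2.46. On the Th1 list, 6 were higher and 1 lower of 25 (6 and 2 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.329 with an estimated correlation), with the cytokine receptor chains Il12rb2 and Ifngr1 up by 2.01 and 1.89, while Tbx21 had a log2 fold change of -0.16 (SE 0.61) and Ifng of 0.42 (SE 0.23). On the cytotoxicity list, 5 were higher and 1 lower of 21 (7 and 4 adjusted over the list alone; camera adjusted p = 0.0466, adjusted p = 0.695 with an estimated correlation), Fasl by 2.58 and the granzyme inhibitor Serpinb9 by 2.45. On the Tfh list, 3 were lower and 1 higher of 27 (4 and 1 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.805 with an estimated correlation). The Tfh list no longer passed without spleen replicate 1 (adjusted p = 0.421), without IEL replicate 1 (0.0901) or 2 (0.0905) or without LPL replicate 1 (0.0604), and the cytotoxicity list without spleen replicate 1 (0.25), IEL replicate 1 (0.0976) or 2 (0.0985) or LPL replicate 2 (0.302). In spleen replicate 1, 11 of the 27 Tfh members were over 2-fold above spleen replicate 2. Btla fell by 1.91, Slamf6 fell by 1.85, and Icos rose by 2.58. By fry, only the residency (adjusted p = 0.00811), egress (0.01) and TGF-beta (0.0132) lists passed in this comparison.

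Over all genes, limma called 517 higher and 724 lower in LPL, with 3186 at an unadjusted p under 0.05. The split depended on scaling: 41.7% of the calls were higher as deposited, 61.5% with median-of-ratios scaling and 52.1% with upper-quartile scaling, which moved the median of all genes by 0.18 and 0.10 on the log2 scale from -0.23. Without spleen replicate 1, spleen replicate 2 or LPL replicate 1, 0 genes were called, without LPL replicate 2 the counts were 42 higher and 8 lower, without IEL replicate 1 they were 141 and 116, and without IEL replicate 2 they were 140 and 115. The enterocyte list had a median log2 fold change of -1.07 in LPL (camera adjusted p = 0.407), a direction that turned without spleen replicate 2 or LPL replicate 1. Without spleen replicate 2, the enterocyte list (adjusted p = 0.043) and the Paneth and goblet list (adjusted p = 0.0093) were higher in LPL, and without spleen replicate 1 both were lower (adjusted p of 5.22e-06 and 0.00407).

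**Figure D2:**
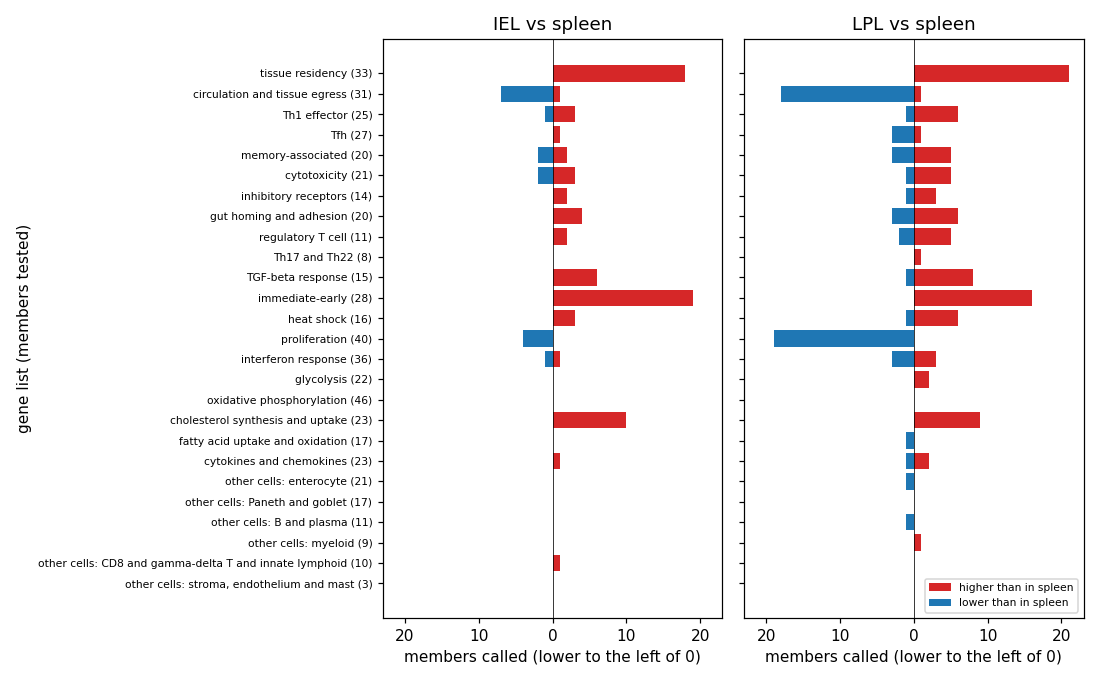
Members of each tested list called higher (right, red) or lower (left, blue) than in spleen by limma, for IEL (left panel) and LPL (right panel), with the number of members tested in brackets. Residency genes were called higher for 18 members in IEL and 21 in LPL, and egress genes lower for 7 and 18.

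Calls of the comparisons with spleen overlapped. Of the genes called, 201 were higher in both intestinal groups, 79 were lower in both and 0 went in opposite directions, where independent lists of these sizes would share 10.6 and 6.13 genes. With each library left out in turn, the counts were 0 to 39 higher and 0 to 21 lower in both, and with only the groups compared in the fit they were 16 and 1. Rgs1, Nr4a2, Ccr9, Tgif1, Insig1 and Dgat1 were among those higher in both, and S1pr1, Klf2, S1pr5, Cdc20 and Arhgef18 among those lower in both. Across genes, which are not independent replicates, the fold changes correlated at r = 0.65 with a covariance of 0.511. In 100 simulations, unchanged groups were set against 1 shared simulated spleen group. The mean r was 0.50 and the mean covariance 0.155, and 0.02 and 0.03 genes on average were called higher and lower in both. The simulated genes were independent and did not hold the differences between the real spleen libraries, so these values are only a rough reference. The spleen libraries were too few to split, so part of the excess may come from the shared controls.

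**Figure D3:**
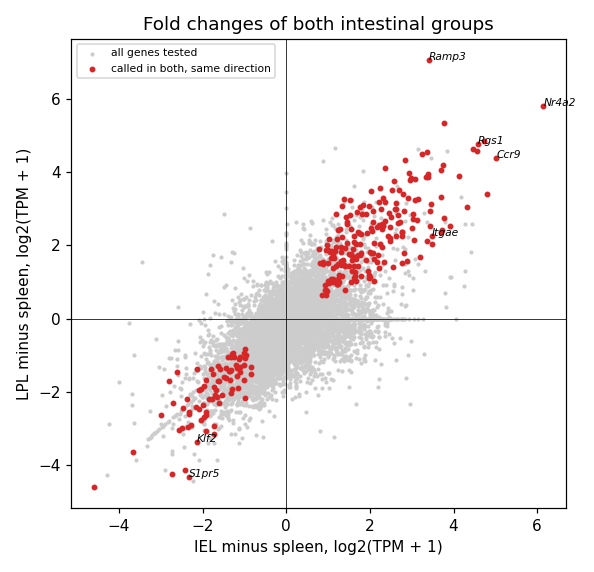
Log2 fold change against spleen of each of 11465 genes in IEL (horizontal) and LPL (vertical), on the log2(TPM + 1) scale; red points are the genes called in both comparisons in the same direction. The red points number 201 higher and 79 lower, and 0 genes were called in opposite directions.

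The third comparison set IEL directly against LPL. No gene passed the threshold (0 higher and 0 lower by limma), although 1632 genes had an unadjusted p under 0.05 where 573 would be expected by chance. This depended on the model: with the replicate number as a block, 147 genes were higher and 124 lower. The labels do not say that the number marks a shared animal or day, and deviations of same-numbered IEL and LPL libraries correlated at 0.13. Ramp3 had a log2 fold change of -3.65 (SE 0.31, adjusted p = 0.0556), at 39.6 ± 1.6 TPM in IEL and 520 ± 155 in LPL. Other differences below the threshold were Irf1 at 1.36 (adjusted p = 0.0773), Ifngr1 at -1.10 (adjusted p = 0.0773), Tnfrsf4 at -1.73 (adjusted p = 0.0807), Cxcr6 at -1.01 (adjusted p = 0.0813) and Cdc20 at 1.43 (adjusted p = 0.0813). Itgae differed by 1.23 (adjusted p = 0.23) and Cd69 by 1.31 (adjusted p = 0.0996). By camera, 7 of 26 lists differed, 4 higher and 3 lower in IEL, and with an estimated correlation 0 did (smallest adjusted p = 0.793). Without IEL replicate 2, 182 genes were called higher and 8 lower in IEL, and 0 without any other single library. IEL replicate 1 was also the library in which 840 genes exceeded 5 TPM and lay over 2-fold above each other library, against 21 to 137 genes for the others. Without IEL replicate 2, IEL rested on that library alone, so the calls of that fit do not separate the tissue from the library.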

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

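The fixed lists were tested for a difference between the intestinal groups themselves, and 7 passed camera at the preset correlation, while with an estimated correlation 0 of the 7 passed (adjusted p = 0.793 for each). At the preset correlation, the immediate-early list (adjusted p = 0.000544), the egress list (0.0065), the proliferation list (0.01) and the enterocyte markers (0.0065) were higher in IEL than in LPL, and the Th1 list (0.01), the regulatory T cell list (0.0065) and the memory-associated list (0.0198) were lower. None of their members passed limma's threshold over all genes (0 genes). Adjusted over each list alone, 9 immediate-early, 5 egress and 1 proliferation member were higher, 1 Th1 member was higher and 6 lower, and 4 regulatory T cell members were lower. With libraries left out in turn, the egress result passed in the same direction in 5 of 6 fits, the immediate-early and regulatory T cell results in 4, the Th1, memory-associated and enterocyte results in 3 and the proliferation result in 2. The direction of the proliferation list turned without IEL replicate 2 (adjusted p = 0.33).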

How the results depend on the processing

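Fits without the mean-variance trend, with array weights, without small RNA rows and with a mean of at least 10 TPM were chosen after seeing the data; the DESeq2 Wald test and limma voom, planned for counts, were not run on TPM. In what follows, counts are given as higher then lower, first for IEL against spleen (235 and 97), then LPL against spleen (517 and 724), then IEL against LPL (0 and 0), then both intestinal groups against spleen (201 and 79). Leaving out each library in turn gave 0 to 227 and 0 to 35, and 0 to 141 and 0 to 116. Next in that order came 0 to 182 and 0 to 8, and 0 to 39 and 0 to 21. A lone library is then assumed to vary like the other groups, and the model has fewer libraries. The simulated data were fitted at that size only for IEL against spleen without spleen replicate 1, where they still gave calls. Their genes were drawn from the fitted spreads, so they cannot decide whether lost power explains the fall in calls. Fitting only the libraries of the groups compared gave 22 and 1, 142 and 117, 0 and 0, and 16 and 1. Testing against a log2 fold change of 1 gave 39 and 1, 96 and 20, 0 and 0, and 31 and 0. Without the trend the counts were 57 and 21, 212 and 224, 1 and 3, and 44 and 16. The replicate numbers are not said to mark a shared animal or day, and deviations of same-numbered libraries correlated at -0.02, 0.18 and 0.13, so the numbers were not taken to pair the libraries, although some replicate differences had 1 sign in all 3 tissues, such as the Bcl6 ratios of 1.67, 1.77 and 1.61; a replicate block gave 407 and 326, 752 and 1281, 147 and 124, and 334 and 263, and moved the lists past the threshold in IEL against spleen from 8 to 14. Median-of-ratios scaling lowered the lower calls to 61, 449 and 45 and gave 8 lower in IEL against LPL, and array weights gave 60 and 1220 lower in the comparisons with spleen. A pseudocount of 0.1 gave 51 lower in both. In IEL against LPL, 1 gene was lower with upper-quartile scaling, with a mean of at least 1 TPM and without markers of other cells, and 6 were lower without small RNA rows and with a mean of at least 10 TPM. Lists past the threshold numbered 8, 11 and 7 in the 3 comparisons, 0, 0 and 0 with an estimated correlation, 5, 3 and 0 with fry, 3 in IEL against LPL with a mean of at least 10 TPM, and 8 to 12, 9 to 14 and 2 to 10 with libraries left out. Directions that turned with a library left out, where the main fit or the other fit passed, were those of the enterocyte markers in IEL against spleen (adjusted p of 1.31e-07 to 0.727) and in LPL against spleen (5.22e-06 to 0.941), the Paneth and goblet markers in LPL against spleen (0.00407 to 0.913) and the proliferation list in IEL against LPL (7.04e-07 to 0.933). No named gene that was called turned its direction (0 in any fit); of 145 such calls, 139 passed with median-of-ratios scaling, 44 with only the groups compared and 0 without spleen replicate 1 or spleen replicate 2. The cause was not tested, except that fits with fewer libraries have fewer degrees of freedom. Low depth in IEL, where 1 read was worth 0.36 and 0.29 TPM at 2000 bp, and in LPL replicate 2 (0.28), limits what can be said of low genes.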

Other observations

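The tests in this part were all chosen after the values were seen, and the genes named in it outside the fixed rule were chosen in the same way. In spleen, a set of genes of the fixed Tfh list was higher in replicate 1 than in replicate 2. Of 27 tested members, 11 were over 2-fold higher in replicate 1 and 0 over 2-fold lower, whereas 5.49% of all 11465 genes were over 2-fold higher. Cxcr5, the follicle homing receptor, was at 119 TPM against 2.67, Tox2 at 30.3 against 0.362, Id3 at 115.7 against 12.7 and Tcf7 at 413.5 against 56.4. The other 4 libraries held between 0 and 2.79 TPM of Cxcr5.

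B cells in spleen replicate 1 were set against this pattern. The B and plasma markers went the other way, with a median log2 difference of -0.99 and 10 of 11 members lower in replicate 1. The member that was higher there was Cd22, at 18.2 TPM against 10.4. Because spleen replicate 2 also held epithelial transcripts, it is not a clean reference for this comparison. A replicate difference shared by all 3 tissues stays open: the median log2 difference over all 27 members was 0.63 in spleen, 0 in IEL and -0.01 in LPL, but members went both ways in IEL (12 higher and 13 lower in replicate 1) and LPL (12 and 14). Of the 11 genes, 0 were over 2-fold higher in replicate 1 in IEL or LPL, where 7 of them had means under 5 TPM; among the others, Tcf7 was higher and Slamf6 lower in replicate 1 in both. T cells with an intact Bcl6 allele in spleen replicate 1 are a candidate explanation that also stays open, because gene-level TPM do not separate exons; total Bcl6 was 1.67 times as high in spleen replicate 1 as in replicate 2, and the ratio was 1.77 in IEL and 1.61 in LPL. The design has no group that would test a biological explanation.

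Residency and immediate-early genes were higher in both intestinal groups, and the fixed lists overlap. The residency list did not rise only through members shared with the immediate-early and heat shock lists: the other 28 members had median log2 fold changes of 1.90 in IEL and 1.95 in LPL, with 13 and 16 of them called higher. Epithelial RNA is argued against as the source of the rise of the set: in the pairs of an intestinal and a spleen library where the epithelial markers were not higher (2 of 4 pairs for IEL, both with spleen replicate 2, and 3 of 4 for LPL), the 56 residency and immediate-early genes still had a median log2 difference of at least 2.13 for IEL and 1.69 for LPL. The 38 markers together held 356 and 662 TPM in the IEL libraries, where the 56 genes held at least 18100 TPM more than in a spleen library. Other epithelial transcripts were not summed, so the argument rests on the pairs and not on this sum. A response to tissue handling may contribute and cannot be told apart from the tissue, because no control for the isolation of a tissue is among the 6 libraries; the immediate-early list had a median of 2.73 in IEL. The tissue itself stays among the open explanations.

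Intestinal epithelial transcripts were present in spleen replicate 2. Zg16, a goblet cell product, was at 158 TPM there and 1.23 in spleen replicate 1, and Apoa1, an enterocyte apolipoprotein, at 112.9 and 0. Read cross-talk from the other 5 libraries is argued against, since 24 of the 38 epithelial markers were higher in spleen replicate 2 than in each of the others. A condition shared by the replicate 2 libraries may have contributed: the median log2 difference of replicate 2 over replicate 1 was 3.58 in spleen, 1.67 in LPL and 0.52 in IEL, the last only just above the bound of 0.5 set for it after these libraries had been looked at. No biological explanation was tested.

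In IEL replicate 1, 338 olfactory, vomeronasal and taste receptor genes had a median of 7.54 TPM, against 0.949 in spleen replicate 2 and 0 in the other 4 libraries, and 325 of them were highest in that library. The source of these reads was not tested. The 38 epithelial markers had a lower median there, 5.45 TPM. In fits without IEL replicate 2, IEL rested on this library alone. Higher values of low genes in those fits, and in IEL means, therefore cannot be assigned to the T cells.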
